A study of Homo sapiens with 6 samples.

How the data were processed

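RNA-seq of poly-A selected RNA from MOLM-13 cells, a human acute myeloid leukaemia line, was analysed in 6 libraries. There were 2 control libraries without doxycycline, and 2 libraries each from cells carrying an inducible CaMK2D knockout (KO) vector after 3 and 5 days of doxycycline. Groups were taken from the labels. The labels do not say whether libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The controls differ from the KO-labelled libraries in vector and doxycycline at once, and possibly in time in culture, which the labels do not give. The 3 and 5 day groups differ in doxycycline exposure and in time since induction at once.

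The deposited table holds raw read counts and FPKM values for 24878 genes, with one column of each per library, per the file headers. HISAT2, HTSeq 0.11.2 and DESeq2 1.26.0 and the GRCh38 genome build are named in the submitters' processing notes, with no role or order given. The annotation and counting options are not given in the sources used here. All 24878 gene identifiers and names were found in GENCODE release 29, which was used for coordinates and gene classes. The deposited FPKM values equal the count divided by the table total and by a whole-number gene length, and for 99.7% of genes that length matched the summed exon length of GENCODE release 29 to within 0.5 bases. No gene in the table had 0 counts in every library. The library kit named in the labels is not stated to keep strand, so reads of overlapping or antisense genes cannot be told apart, and genes with near-identical copies are uncertain.

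Total counts ranged from 15456770 to 21081298 per library. A count of 0 allows a level of up to 0.194 CPM in the shallowest library (3 counts), which covers counting error only. Libraries of a group were compared over genes with at least 20 counts in the pair. The chi-square over its degrees of freedom was 37.7 for the controls, 17.4 for day 3 and 23.3 for day 5, so no pair was a repeat deposit within sampling noise.

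Counts as deposited were analysed with edgeR 4.0.16 in R 4.3.3. Genes passing filterByExpr (minimum count 10, minimum total 15) were kept, which left 14601 genes holding at least 99.9% of the counts of each library. TMM factors ranged from 0.962 to 1.04. One model with the 3 groups and no block was fitted, with the robust quasi-likelihood test, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The fit had 3 residual degrees of freedom and a median prior of 5.12. Log2 fold changes carry a prior count of 0.125, and their standard errors (SE) were computed as the absolute log2 fold change over the square root of F. Levels are TMM-scaled CPM, given as mean ± SD of 2 libraries.

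A set of 27 gene lists was fixed before the data were examined. Of 587 memberships, 528 were found in the table. Lists with at least 5 tested members, 26 in all, were tested with camera at a preset correlation of 0.01, with adjustment over the lists within each comparison. The MHC class II list had 4 tested members and was not tested. Further lists, chosen after the data were seen, are given with the closing observations.

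Named genes followed a rule fixed at the same time. It took the CAMK2 genes, and the 8 largest rises and 8 largest falls against control. These had to be protein-coding, past the threshold, at a mean of at least 5 CPM, with both KO-labelled libraries on the same side of both controls, and without clone-based, numbered-locus, antisense or pseudogene names. It also took up to 5 of each direction between the days by the same criteria, and up to 4 members of each list with the smallest adjusted p against control. Some genes that the rule takes are not reported here. Other genes named here were chosen from the lists after their values were seen.

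The test was tested on simulated data drawn from the real means and library sizes with 200 changed genes. For day 3 against control it recovered 36.2% of 94 genes changed 2-fold and 66.3% of 98 changed 4-fold. It made 12 false calls among 14174 genes. For day 5 against control the shares were 44.8% of 96 and 70.2% of 94, with 11 false calls among 14151 genes. For day 5 against day 3 they were 37.4% of 99 and 69.1% of 94, with 8 false calls among 14132 genes. As a share of the genes called, the false calls exceeded the adjusted p threshold in each comparison.

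The alternatives were relative log expression and upper-quartile factors, no filter, a filter of 5 CPM in at least 2 libraries, DESeq2 1.42.0 (genes only), fits of only the groups compared, the replicate number as a block, and leaving out each library. The deposited FPKM values were also tested with limma 3.58.1 on log2(FPKM + 1) and log2(FPKM + 0.1) at a mean FPKM of at least 0.5, and on log2(FPKM + 1) without a filter. Lists were also tested with estimated correlations and with fry. Removing trends with GC content and gene length was added after seeing the data. Reads over the CaMK2D guide site were not analysed here.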

Results

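MOLM-13 cells, a human acute myeloid leukaemia line of the monocytic type, were profiled by RNA-seq in 3 groups of 2 libraries. The groups were control cells without doxycycline, and cells with a doxycycline-inducible CaMK2D knockout (KO) vector after 3 or 5 days of induction. Total counts were 15456770 and 21081298 in the controls, 19473291 and 18919951 at day 3, and 17410879 and 17638179 at day 5. Genes with at least 1 count numbered 19864 and 20790 in the controls, 18538 and 18673 at day 3, and 18996 and 17300 at day 5. The comparisons ask which transcripts differ after induction of the knockout of CaMK2D, a calcium/calmodulin-dependent kinase, and whether they differ between the days.

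The targeted gene was examined first. CAMK2D (ENSG00000145349) lies on chromosome 4 at 113451032 to 113761927 on the minus strand of GRCh38 (GENCODE release 29). Its exonic counts were 18.7 ± 6.03 CPM in the controls (SD, n = 2), 15.2 ± 0.645 at day 3 and 28.6 ± 0.597 at day 5. Per library, CAMK2D stood at 23.0 and 14.5 CPM in the controls, 14.7 and 15.6 at day 3, and 28.98 and 28.1 at day 5. The log2 fold change was -0.30 (SE 0.24, edgeR adjusted p = 0.437) at day 3 and 0.61 (SE 0.23, edgeR adjusted p = 0.118) at day 5, so neither passed the threshold. Without control replicate 1, CAMK2D at day 5 passed it, at 0.97 (edgeR adjusted p = 0.0317), and the day 3 value turned to 0.07. The mRNA level therefore does not mark the knockout, which need not lower it, and the libraries are called KO-labelled from here on. CAMK2G, whose counts exceeded those of CAMK2D and CAMK2B, stood at 80.7 ± 0.392 CPM in the controls, 68.5 ± 9.91 at day 3 and 69.0 ± 4.28 at day 5. It had log2 fold changes of -0.24 and -0.23 and edgeR adjusted p of 0.313 and 0.322. CAMK2B was low and uneven, at 0.385 and 4.51 CPM in the controls, with log2 fold changes of -2.24 (SE 1.37, edgeR adjusted p = 0.329) and -2.76 (SE 1.42, edgeR adjusted p = 0.239). It passed the threshold at day 5 without a low-count filter (-2.81, edgeR adjusted p = 0.0105). Of the 11 tested members of the CaMK and calmodulin list, 0 passed the edgeR threshold at either day, over all genes or adjusted over the list alone. With the replicate number as a block, CAMK2D (higher) and CAMKK2 (lower) passed it over all genes at day 5.

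**Figure D1:**
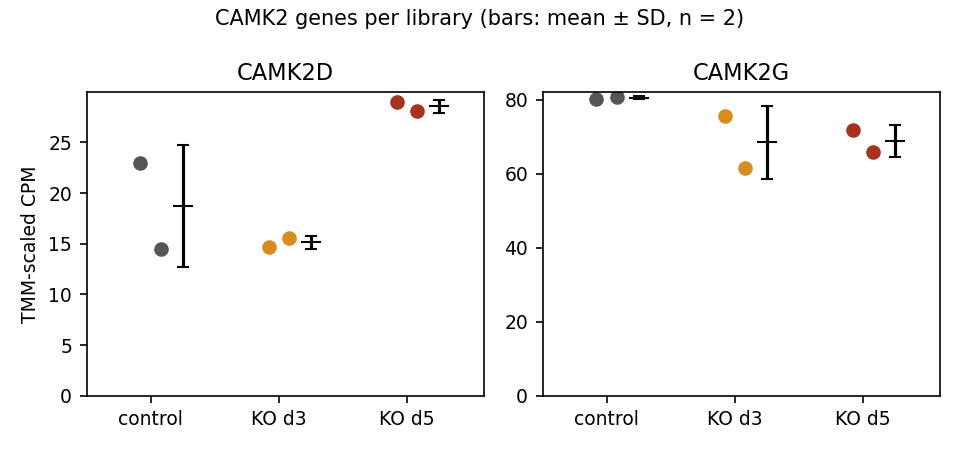
TMM-scaled CPM of CAMK2D and CAMK2G in each library (points) by group, with mean ± SD (n = 2). The KO-labelled day 3 libraries lie within the CAMK2D range of the controls (14.5 to 23.0), and the day 5 libraries lie above it.

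At day 3 the named genes with the largest changes included MPO, FADS2 and CHI3L1, which were lower, and KLHDC7B and GDF15, which were higher. MPO, the myeloperoxidase of neutrophil and monocyte granules (chromosome 17, 58269856 to 58280935), fell from 941 ± 394 to 22.1 ± 7.91 CPM. FADS2, a fatty acid desaturase, fell from 111 ± 13.0 to 8.81 ± 2.66 CPM, and CHI3L1, a secreted chitinase-like glycoprotein, from 1067 ± 199 to 97.0 ± 3.64 CPM. RNF175, ROS1, AQP3, TMEM105 and TNR fell by 3.70 to 4.28 on the log2 scale. KLHDC7B (chromosome 22, 50545891 to 50551023), at 2 to 3 counts in the controls, rose from 0.136 ± 0.0108 to 28.0 ± 7.63 CPM (edgeR adjusted p = 0.000208). GDF15, a stress-induced cytokine of the TGF-beta family, rose from 4.01 ± 0.303 to 82.2 ± 12.2 CPM. SDC3, IFIT2, ARRDC3, DHX58, IFIT5 and SDSL rose by log2 fold changes of 2.97 to 4.85.

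In all, 1710 of 14601 genes passed the edgeR threshold at day 3, 835 higher and 875 lower. The count was 282 without KO day 3 replicate 1, 333 without KO day 3 replicate 2 and 1059 without control replicate 1, where the lone library of a group is assumed to vary like the other groups. MPO missed the threshold without control replicate 1 or 2 (edgeR adjusted p = 0.0636 and 0.0502) or KO day 3 replicate 1 or 2 (edgeR adjusted p = 0.0726 and 0.0611). TMEM105 missed it without control replicate 2 (edgeR adjusted p = 0.0645) or KO day 3 replicate 1 or 2 (0.111 and 0.0528). TNR missed it without control replicate 1 (edgeR adjusted p = 0.0869), KO day 3 replicate 1 or 2 (0.0579 and 0.124), or KO day 5 replicate 1 or 2 (0.083 and 0.0772). DHX58 missed it without control replicate 1 (edgeR adjusted p = 0.0583). IFIT5 missed it without control replicate 1 or 2 (edgeR adjusted p = 0.204 and 0.188), KO day 3 replicate 2 (0.0989), or KO day 5 replicate 1 or 2 (0.0638 and 0.0571). SDC3 missed it with limma on log2(FPKM + 1) with and without a filter (adjusted p = 0.0963 and 0.2). FADS2 overlaps FADS1 and FEN1, ARRDC3 an antisense gene and SDSL the gene SDS, and their reads cannot be told apart without strand or exon detail.

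Cholesterol synthesis and uptake genes fell together at day 3. Of 20 tested members 18 fell and 0 rose, both over all genes and adjusted over the list alone, with a median log2 fold change of -1.30 (camera adjusted p = 1.08e-36). This was the only list at day 3 still past the threshold with an estimated correlation (adjusted p = 0.0446). ACAT2, an acetyl-CoA acetyltransferase, fell from 104 ± 2.11 to 19.6 ± 0.627 CPM, and INSIG1, a sterol-responsive regulator, from 385 ± 14.4 to 89.9 ± 3.07 CPM. At day 5, 16 members fell (18 adjusted over the list alone), with a median of -1.02 (camera adjusted p = 2.73e-26), which was lost with an estimated correlation (adjusted p = 0.0748). INSIG1 was then 85.2 ± 1.72 CPM and ACAT2 27.5 ± 1.08 CPM. ACAT2 overlaps TCP1 and SOD2.

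Mitochondrially encoded mRNAs fell unevenly at both days. Of 13 tested, 10 fell and 0 rose at day 3 (the same counts adjusted over the list alone), with a median log2 fold change of -1.36 (camera adjusted p = 8.6e-22, and adjusted p = 0.183 with an estimated correlation). MT-CO2 and MT-CO1, which encode subunits of cytochrome c oxidase, fell from 4431 ± 499 to 742 ± 89.6 CPM and from 7951 ± 1136 to 1696 ± 132 CPM. MT-CO3 and MT-CYB fell by 2.29 (SE 0.18) and 1.68 (SE 0.14) on the log2 scale. MT-ND5 and MT-ND6 had log2 fold changes of 0.11 (SE 0.17, edgeR adjusted p = 0.706) and 0.31 (SE 0.19, edgeR adjusted p = 0.308), and MT-ATP8 was also not past the threshold. At day 5, 10 fell and 0 rose (10 and 2 adjusted over the list alone), with a median of -1.12 (camera adjusted p = 1.4e-14, and adjusted p = 0.203 with an estimated correlation), and MT-CO2 stood at 737 ± 41.8 CPM. Mitochondrial genes held 2.79% ± 0.374 of all counts in the controls, 0.899% ± 0.0434 at day 3 and 1.11% ± 0.0421 at day 5 (SD, n = 2). MT-CO3 shares bases with MT-ATP6, and nuclear copies of these genes make single values uncertain.

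**Figure D2:**
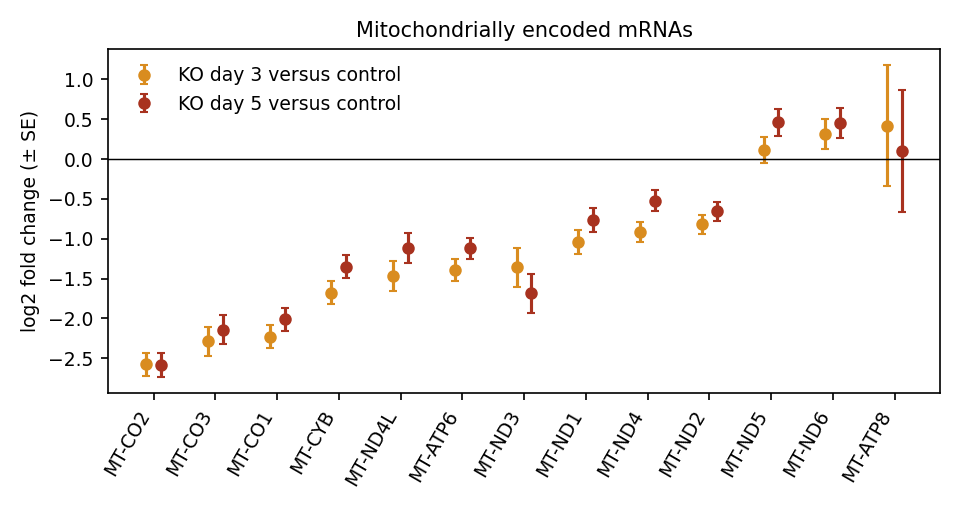
Log2 fold change against control (± SE, from the fit of 6 libraries) of each mitochondrially encoded mRNA at day 3 and day 5. Values run from -2.59 for MT-CO2 at day 5 to above 0 for MT-ND5, MT-ND6 and MT-ATP8, which did not pass the threshold.

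Myeloid effector genes were lower at day 3. Of 13 tested granule genes 4 fell and 0 rose (5 and 0 adjusted over the list alone). Their median log2 fold change was -1.43 (camera adjusted p = 3.31e-08, and adjusted p = 0.183 with an estimated correlation). RNASE2, a granule ribonuclease, fell from 502 ± 81.7 to 55.6 ± 15.03 CPM, and AZU1 from 1640 ± 202 to 549 ± 125 CPM. Of 20 monocyte and macrophage markers 7 fell and 1 rose (13 and 2 adjusted over the list alone). Their median was -1.72 (camera adjusted p = 3.31e-08, and adjusted p = 0.207 with an estimated correlation). TLR2 and TLR4, receptors for bacterial ligands, fell by 2.09 (SE 0.18) and 2.91 (SE 0.37) on the log2 scale, and FCGR2A, an Fc receptor, by 1.90 (SE 0.23). CTSD, a lysosomal protease, rose by 0.94 (SE 0.155), a call lost without KO day 3 replicate 1 or 2 (edgeR adjusted p = 0.0602 and 0.0802). Of 16 surface antigens of acute myeloid leukaemia 7 fell and 1 rose (8 and 1 adjusted over the list alone). Their median was -0.57 (camera adjusted p = 0.000135, and adjusted p = 0.183 with an estimated correlation). FLT3, a receptor tyrosine kinase, fell from 969 ± 132 to 334 ± 9.33 CPM, CD82 fell by 2.46 (SE 0.22) on the log2 scale, and CD38 rose by 1.80 (SE 0.22).

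JAK-STAT targets and lymphoid markers were also lower as lists at day 3. JAK-STAT targets fell in 6 of 16 and rose in 0 (7 and 1 adjusted over the list alone; camera adjusted p = 0.00106, and adjusted p = 0.561 with an estimated correlation). PIM2, a survival kinase, and SOCS1, a feedback inhibitor that overlaps RMI2, fell, with log2 fold changes of -1.47 (SE 0.17) and -2.80 (SE 0.35). Lymphoid markers fell in 3 of 8 and rose in 0 (4 and 0 adjusted over the list alone; camera adjusted p = 0.00549, and adjusted p = 0.207 with an estimated correlation). The list missed the threshold at 5 CPM in at least 2 libraries (camera adjusted p = 0.0889) and with limma on log2(FPKM + 1) (0.0748). The genes that fell included NKG7, a granule protein of cytotoxic lymphocytes, and TRAC, a T cell receptor chain. Both missed the threshold without control replicate 1 (edgeR adjusted p = 0.167 and 0.224), KO day 3 replicate 1 (0.0685 and 0.135) or KO day 3 replicate 2 (0.239 and 0.232). NKG7 also missed it without KO day 5 replicate 1 or 2 (0.0675 and 0.0668).

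Growth and stress genes were higher at day 3. Of 29 MYC target and ribosome biogenesis genes 14 rose and 1 fell (20 and 1 adjusted over the list alone). Their median log2 fold change was 0.50 (camera adjusted p = 1.82e-09, and adjusted p = 0.207 with an estimated correlation). RRP9, a factor for ribosomal RNA processing, rose from 58.7 ± 7.36 to 138 ± 1.83 CPM, and ODC1, the first enzyme of polyamine synthesis, from 111 ± 17.6 to 291 ± 17.02 CPM. MYC itself rose from 609 ± 7.54 to 1002 ± 156 CPM, a call lost without KO day 3 replicate 2 (edgeR adjusted p = 0.15). Of 25 ATF4 and unfolded protein response genes 11 rose and 1 fell (11 and 2 adjusted over the list alone). Their median was 0.28 (camera adjusted p = 3.76e-08, and adjusted p = 0.207 with an estimated correlation). TRIB3, a stress-induced pseudokinase, rose from 200 ± 19.1 to 799 ± 5.95 CPM, and HSPA5, the chaperone of the endoplasmic reticulum, from 387 ± 18.0 to 962 ± 42.5 CPM.

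Interferon-stimulated genes were higher as a list at day 3, with libraries far apart. Of 27 tested, 1 rose and 0 fell (1 and 0 adjusted over the list alone). The median was 2.01 (camera adjusted p = 9.31e-08, and adjusted p = 0.561 with an estimated correlation of 0.917). The gene was IFIT2, an interferon-induced RNA-binding protein, at 2.12 and 2.73 CPM in the controls and 29.1 and 88.6 CPM at day 3. IFIT2 missed the threshold without control replicate 1 or 2 (edgeR adjusted p = 0.258 and 0.205). IFIT1, IFIT3 and OASL stood at 76.9, 105 and 67.2 CPM in KO day 3 replicate 2 and at 12.1, 28.0 and 13.9 CPM in replicate 1, and missed the threshold. IFIT1, IFIT2 and IFIT3 overlap LIPA. DHX58 and IFIT5, named above among the largest rises at day 3, passed the threshold but are not members of this list.

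G2/M genes were lower as a list at day 3 (median log2 fold change -0.33, camera adjusted p = 0.0497, and adjusted p = 0.753 with an estimated correlation). This was lost without control replicate 1 or KO day 3 replicate 2 (camera adjusted p = 0.195 and 0.377), and with upper-quartile factors (0.0536). BUB1B and CENPA fell and CDC20 rose (2 and 1 also adjusted over the list alone). All 3 missed the threshold without control replicate 1 (edgeR adjusted p = 0.1, 0.0676 and 0.184), KO day 3 replicate 1 (0.158, 0.112 and 0.152) or KO day 3 replicate 2 (0.196, 0.271 and 0.0622). CENPA and CDC20 also missed it without control replicate 2 (edgeR adjusted p = 0.139 and 0.117).

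At day 5 several genes named at day 3 were again among the extremes. KLHDC7B reached 36.0 ± 6.29 CPM and GDF15 232 ± 100.8 CPM. HMOX1, the haem oxygenase (chromosome 22, 35380361 to 35394214), rose from 0.944 ± 0.427 CPM in the controls to 86.9 ± 17.01, a log2 fold change of 6.47 (SE 0.32, edgeR adjusted p = 0.000125). SDC3, ARRDC3, IFIT2, RETREG1 and UNC5B rose by log2 fold changes of 3.58 to 5.55. MPO fell to 11.2 ± 6.17 CPM, and NAV3, a cytoskeletal regulator, from 140 ± 17.8 to 6.79 ± 1.36. RNF175, TNR, CD180, HAL, TMEM105 and ADAMTS14 fell by 3.65 to 4.81 on the log2 scale.

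In all, 2117 of 14601 genes passed the edgeR threshold at day 5, 1087 higher and 1030 lower. The count was 914 without KO day 5 replicate 1, 723 without KO day 5 replicate 2, 1370 without KO day 3 replicate 1 and 1315 when only the 4 libraries compared were fitted. IFIT2 missed the threshold without control replicate 1 or 2 (edgeR adjusted p = 0.254 and 0.227) or KO day 5 replicate 1 or 2 (0.0587 and 0.0888). TNR missed it without KO day 5 replicate 1 or 2 (edgeR adjusted p = 0.118 and 0.158), and TMEM105 without either (0.123 and 0.0828) or control replicate 2 (0.0684). CD180 and ADAMTS14 missed it without control replicate 1 (edgeR adjusted p = 0.0874 and 0.119) or control replicate 2 (0.0749 and 0.11).

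Myeloid lists were lower at day 5. Granule genes fell in 6 of 13 and rose in 0 (7 and 1 adjusted over the list alone). Their median log2 fold change was -1.34 (camera adjusted p = 5.56e-09, and adjusted p = 0.203 with an estimated correlation). Monocyte markers fell in 7 of 20 and rose in 2 (13 and 2 adjusted over the list alone; camera adjusted p = 1.15e-06, and adjusted p = 0.323 with an estimated correlation). Surface antigens fell in 7 of 16 and rose in 2 (9 and 3 adjusted over the list alone; camera adjusted p = 0.000258, and adjusted p = 0.203 with an estimated correlation), with FLT3 at 255 ± 19.5 CPM. JAK-STAT targets fell in 5 of 16 (5 adjusted over the list alone; camera adjusted p = 0.00231, and adjusted p = 0.672 with an estimated correlation). This was lost without KO day 5 replicate 1 (camera adjusted p = 0.0857). Lymphoid markers fell in 3 of 8 (5 adjusted over the list alone; camera adjusted p = 0.0018, and adjusted p = 0.204 with an estimated correlation). The list of epithelial, stromal and HEK293-type markers fell (median -0.40, camera adjusted p = 0.0432, and adjusted p = 0.648 with an estimated correlation), with 2 of 7 members lower (2 adjusted over the list alone). They were PECAM1, an adhesion molecule of endothelial and myeloid cells, and WT1, a transcription factor also made in leukaemia. The list missed the threshold without control replicate 1 or KO day 5 replicate 1 or 2 (camera adjusted p = 0.125, 0.0893 and 0.101) and without a filter (0.0926), and WT1 without KO day 5 replicate 2 (edgeR adjusted p = 0.0634).

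Stress genes were higher and genes of the G1/S transition lower at day 5. ATF4 and unfolded protein response genes rose in 9 of 25 and fell in 1 (12 and 3 adjusted over the list alone; camera adjusted p = 1.15e-06, and adjusted p = 0.323 with an estimated correlation). TRIB3 stood at 996 ± 84.2 CPM, and DNAJB9, a chaperone, rose from 12.4 ± 1.04 to 42.8 ± 5.69 CPM. Genes of the G1/S transition fell in 5 of 26 (5 adjusted over the list alone; median -0.65, camera adjusted p = 1.35e-05, and adjusted p = 0.672 with an estimated correlation). Among them UNG, a DNA repair glycosylase, fell by 1.07 (SE 0.16) on the log2 scale. CCNE1, MCM7 and CDT1 were also called. Leaving out each library gave -1.581 to -0.973 for CCNE1, -0.915 to -0.438 for MCM7 and -1.311 to -0.9 for CDT1. Targets of p53 rose in 4 of 27 and fell in 1 (5 and 1 adjusted over the list alone; median 0.63, camera adjusted p = 9.09e-05, and adjusted p = 0.672 with an estimated correlation). GDF15, SESN2, PLK3 and RRM2B rose, of which SESN2 is also in the ATF4 list, and CD82 fell. PLK3 missed the threshold without KO day 5 replicate 2 (edgeR adjusted p = 0.0867). Interferon-stimulated genes held 1 call, IFIT2 (0 adjusted over the list alone; median 1.37, camera adjusted p = 0.00022, and adjusted p = 0.683 with an estimated correlation).

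**Figure D3:**
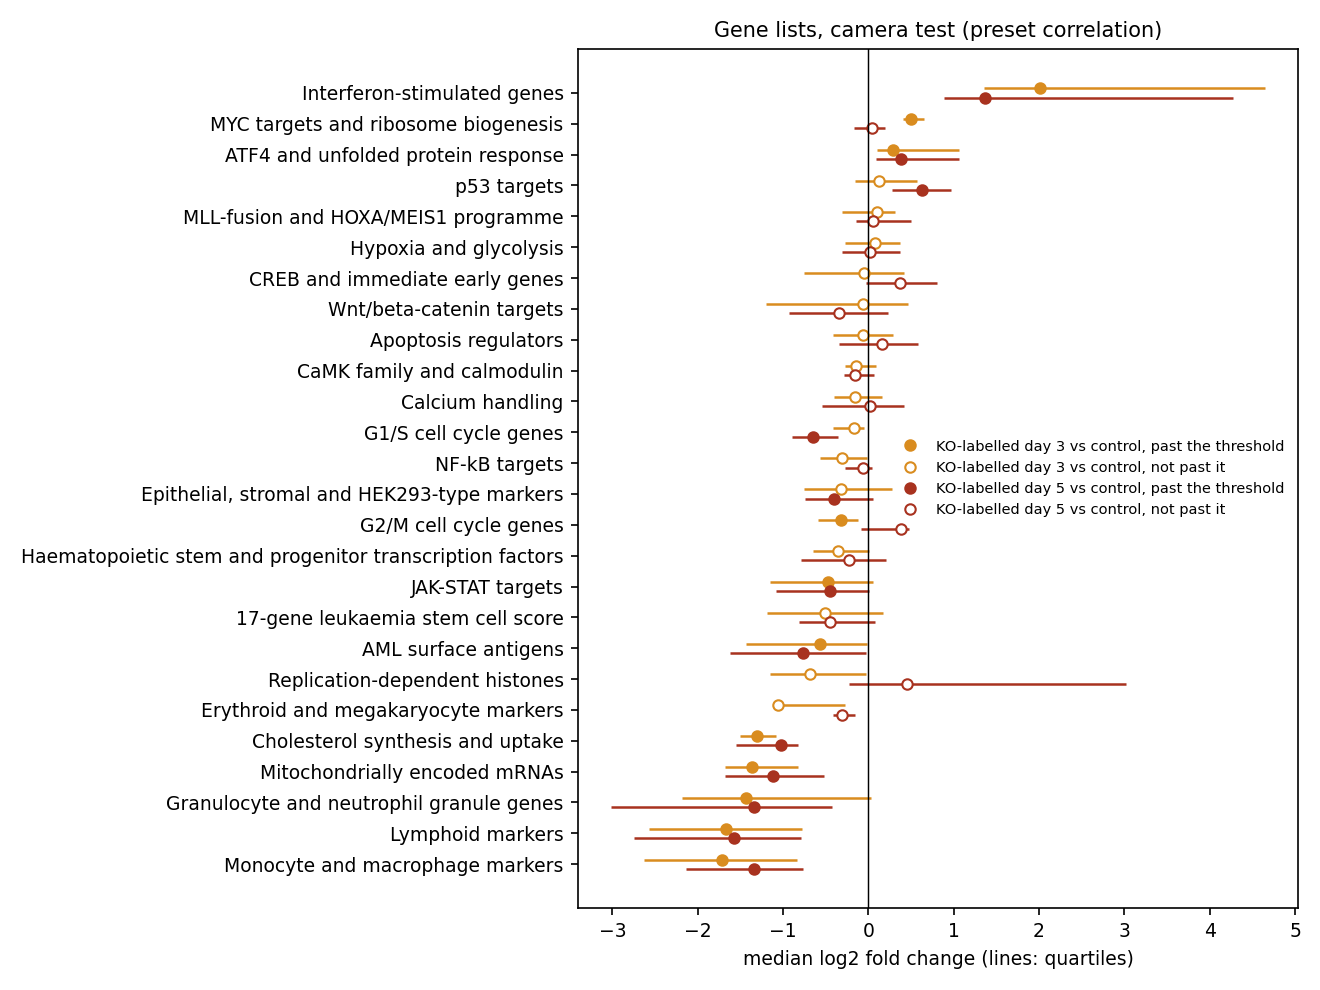
Median log2 fold change against control of the tested members of each of 26 gene lists, with quartiles, at day 3 and day 5; filled points passed camera at the preset correlation. Medians run from 2.01 for interferon-stimulated genes to -1.72 for monocyte and macrophage markers, both at day 3, and with estimated correlations only cholesterol synthesis and uptake at day 3 passed.

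The remaining lists did not pass camera against control at either day. The programme of MLL fusions with HOXA and MEIS1 had camera adjusted p of 0.38 at day 3 and 0.533 at day 5, with medians of 0.10 and 0.06 whose sign differs from the test's direction and from the means of -0.08 and -0.03. Its member MYB, a progenitor transcription factor, fell from 435 ± 34.0 to 208 ± 33.1 CPM at day 5. Haematopoietic transcription factors went both ways (camera adjusted p = 0.212 and 0.139). BMI1 rose from 81.3 ± 7.2 to 195 ± 12.3 CPM at day 5, and RUNX1 fell from 508 ± 104 to 265 ± 8.51 CPM. Calcium handling (camera adjusted p = 0.591 and 0.726) held STIM1, a calcium sensor, which rose from 50.9 ± 7.58 to 126 ± 14.99 CPM at day 5. Hypoxia and glycolysis (camera adjusted p = 0.413 and 0.711) held VEGFA, which rose from 377 ± 11.04 to 779 ± 14.5 CPM at day 3. Apoptosis regulators (camera adjusted p = 0.212 and 0.711) held BMF, a BH3-only protein, which fell by 1.261 (SE 0.14) on the log2 scale at day 3. At day 5 the median of this list was 0.16 while the test pointed down.

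Among the other lists, the camera adjusted p at day 3 and day 5 was 0.304 and 0.544 for leukaemia stem cell score genes, 0.819 and 0.532 for Wnt targets, and 0.0961 and 0.654 for NF-kB targets. It was 0.0763 and 0.509 for erythroid and megakaryocyte markers, 0.323 and 0.276 for histones, 0.522 and 0.0578 for immediate early genes, and 0.591 and 0.711 for CaMK genes. Of 4 measured MHC class II genes, too few for the list test, 0 changed at day 3 (2 lower adjusted over the list alone) and 1 at day 5 (1 adjusted over the list alone). That was CD74, the invariant chain, which fell by 0.98 (SE 0.18, edgeR adjusted p = 0.0136), a call lost without KO day 5 replicate 1 (edgeR adjusted p = 0.0608). Lists that passed at 1 day only had camera adjusted p at the other day of 0.0671 for p53 targets, 0.158 for G1/S genes and 0.0651 for the epithelial list at day 3, and of 0.451 for MYC targets and 0.0911 for G2/M genes at day 5.

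The changes against control at the days overlapped. Among the 14601 genes, 539 were higher and 582 lower at both days, and 1 went opposite ways, where independent lists of these sizes would share 62.2 and 61.7. Across genes, which are not independent replicates, the log2 fold changes had r = 0.808 and a covariance of 0.369. In 20 simulations of unchanged groups, where the controls were also simulated and shared by both comparisons, these were 0.502 and 0.069 on average. Both comparisons use the same 2 controls, which are too few to split, so part of the overlap may come from them.

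Between the days, HMOX1, FTH1, GCLM and TNFRSF10D were higher at day 5. HMOX1 rose from 5.26 ± 0.673 CPM at day 3 to 86.9 ± 17.01, a log2 fold change of 4.04 (SE 0.26, edgeR adjusted p = 0.00443). FTH1, the ferritin heavy chain (chromosome 11, 61959718 to 61967660), rose from 171 ± 5.76 to 633 ± 98.2 CPM (1.89, SE 0.15, edgeR adjusted p = 0.0116), although reads shared with its processed copies make the level uncertain. GCLM, a subunit of the enzyme for glutathione synthesis (chromosome 1, 93885205 to 93909456), rose from 50.3 ± 2.27 to 119 ± 4.57 CPM. TNFRSF10D, a decoy receptor for TRAIL (chromosome 8, 23135588 to 23164030), rose from 86.8 ± 6.96 to 213 ± 17.9 CPM, and both had an edgeR adjusted p of 0.0303.

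These 4 genes passed edgeR and 0 were lower, beside 1249 higher and 957 lower at an unadjusted p under 0.05. DESeq2 called 306 genes, 156 higher and 150 lower. The edgeR fit with the replicate number as a block called 1117, 648 higher and 469 lower. The sample titles carry the letter A for replicate 1 and B for replicate 2 in every group, and the labels do not say what these mark. Deviations of replicate 1 from its group mean correlated at 0.468, 0.399 and 0.544 between the groups. The fit without a block does not take this into account. The edgeR count was 1 without KO day 3 replicate 1, KO day 3 replicate 2 or KO day 5 replicate 2, 14 without control replicate 1 and 15 without control replicate 2. HMOX1 was past the threshold without each library, and missed it with limma on log2(FPKM + 0.1) and on unfiltered log2(FPKM + 1) (adjusted p = 0.0943 and 0.133). FTH1 missed it without KO day 3 replicate 1 or 2 (edgeR adjusted p = 0.157 and 0.19) or KO day 5 replicate 2 (0.0566). GCLM and TNFRSF10D missed it without KO day 3 replicate 1 (edgeR adjusted p = 0.397 and 0.345), KO day 3 replicate 2 (0.425 and 0.499), KO day 5 replicate 1 (0.185 and 0.11) or KO day 5 replicate 2 (0.419 for both). FTH1, GCLM and TNFRSF10D also missed it in all 3 limma fits of FPKM (adjusted p = 0.0867 to 0.413), and GCLM with GC and length trends removed (edgeR adjusted p = 0.122).

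**Figure D4:**
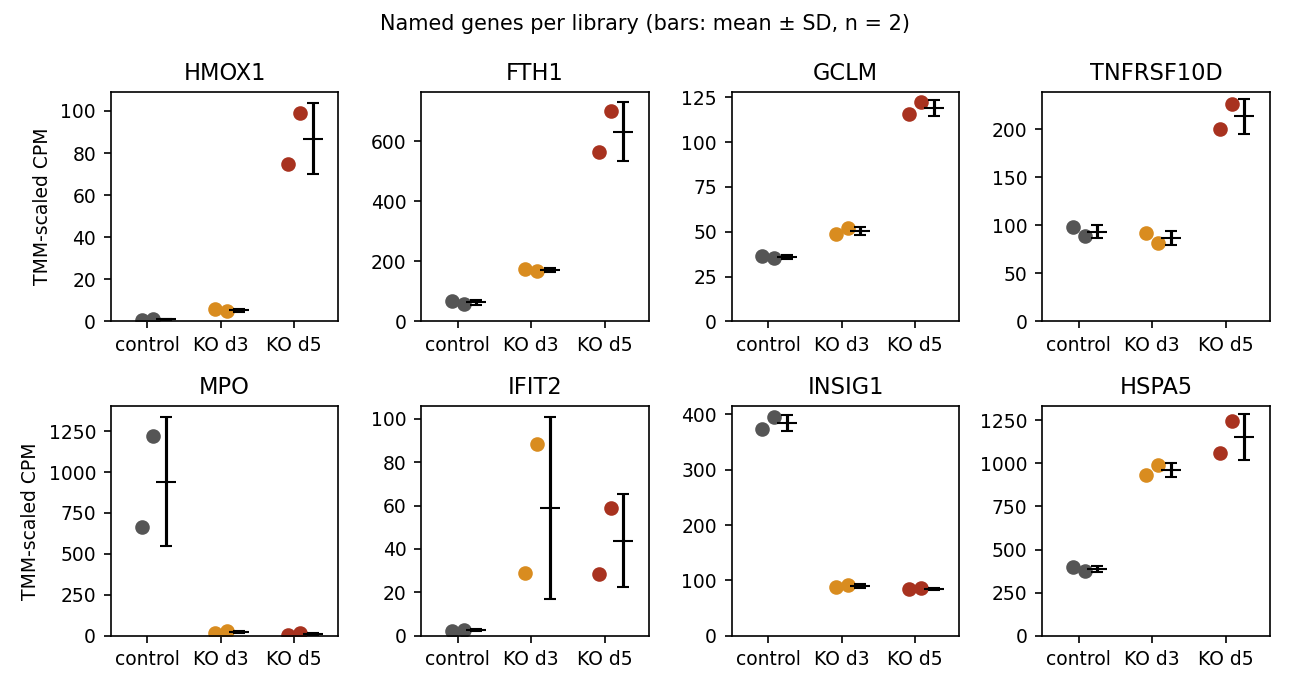
TMM-scaled CPM of 8 genes in each library (points), with mean ± SD (n = 2). HMOX1, FTH1, GCLM and TNFRSF10D are higher at day 5 than at day 3, MPO and INSIG1 are lower and HSPA5 higher at both days than in the controls, and the IFIT2 libraries of one day lie far apart (29.1 and 88.6 CPM at day 3).

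Gene lists also differed between the days, with 0 single members past the edgeR threshold over all genes. MYC target genes were lower at day 5 (median log2 fold change -0.41, camera adjusted p = 3.29e-14, and adjusted p = 0.51 with an estimated correlation), with 15 lower and 1 higher adjusted over the list alone. G2/M genes were higher (0.53, camera adjusted p = 3.2e-10, and adjusted p = 0.758 with an estimated correlation), 8 of them adjusted over the list alone. G1/S genes were lower (-0.36, camera adjusted p = 4.74e-06, and adjusted p = 0.758 with an estimated correlation), 2 of them adjusted over the list alone. Immediate early genes (0.46, camera adjusted p = 1.62e-05), histones (1.257, camera adjusted p = 0.000227) and p53 targets (0.48, camera adjusted p = 0.000445) were higher. Their adjusted p was 0.758, 0.51 and 0.758 with an estimated correlation, and 1, 0 and 5 members were higher adjusted over the list alone. Without KO day 5 replicate 2 the G1/S genes, immediate early genes and p53 targets missed the threshold (camera adjusted p = 0.34, 0.0591 and 0.244), and without KO day 3 replicate 1 so did the p53 targets (0.308). Most replication-dependent histone transcripts lack a poly-A tail, and HIST1H4C stood at 0.404 ± 0.129 CPM at day 3 and 3.08 ± 1.73 at day 5.

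Interferon-stimulated genes were lower at day 5 than at day 3 (median log2 fold change -0.44, camera adjusted p = 0.0396, and adjusted p = 0.861 with an estimated correlation), with 0 of 27 adjusted over the list alone. This was lost with relative log expression or upper-quartile factors (camera adjusted p = 0.0529 and 0.0583), without a filter (0.0598), at 5 CPM in at least 2 libraries (0.0565), with only the compared groups fitted (0.106), with GC and length trends removed (0.0693), and without control replicate 1 or 2 (0.0988 and 0.163). The list turned to higher without KO day 3 replicate 2 or KO day 5 replicate 1, where 1 library was left in a group. With the replicate number as a block it stayed lower (camera adjusted p = 8.3e-05), although the labels do not say what the number marks. The other 19 lists did not pass camera between the days, with adjusted p of 0.0786 for mitochondrially encoded mRNAs and 0.0835 for cholesterol synthesis and uptake.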

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

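In the test of day 5 against day 3, 4 genes and 7 gene lists passed the threshold for a difference between the days; the tests of the spread across mitochondrial mRNAs, of single interferon libraries, of a library swap, of CAMK2G reads and with GC and length trends removed were chosen after the results were seen. The log2 fold changes were 4.04 for HMOX1, 1.89 for FTH1, 1.30 for TNFRSF10D and 1.24 for GCLM. The list medians were -0.41 for MYC targets, 0.53 for G2/M genes, -0.36 for G1/S genes, 0.46 for immediate early genes, 1.257 for histones, 0.48 for p53 targets and -0.44 for interferon-stimulated genes. None of the 7 lists passed with an estimated correlation.

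CAMK2D mRNA was not lower past the threshold in the KO-labelled libraries. A swap of a control with a KO-labelled library is argued against: the lowest correlation within labels exceeded the highest between labels by 0.0094 (0.9732 against 0.9638). Reads of CAMK2G as the only source of the CAMK2D counts are argued against at day 5 when all libraries are used. The log2 fold changes of these genes then differed by 3.07 SE, computed as if the genes were independent. Without control replicate 2 the CAMK2D value at day 5 was 0.283, against 0.611 with all libraries. The difference from CAMK2G in SE was not computed there. At day 3 the log2 fold changes of CAMK2D and CAMK2G differed by -0.247 SE, which does not exclude such reads. A share of CAMK2G reads among the CAMK2D counts is not excluded at either day. Edited transcripts that keep their read count cannot be told apart from a failed knockout here, because 0 columns of the table hold values for single sites.

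Mitochondrially encoded mRNAs were lower in the KO-labelled libraries. A uniform loss of mitochondrial RNA alone is argued against by the spread of the change. It was taken over the 12 such mRNAs at a mean of at least 10 CPM, after the uneven fall was seen. The SD of the change was 0.857 to 1.037 (log2) in the KO-labelled libraries, at least 2.33 times the 0.367 between the controls. A uniform loss as part of the fall is not excluded, and the SD without MT-ND5 and MT-ND6 was not computed. Reads counted at nuclear copies instead are argued against too. The change of 40 such copies was -2.15% of the loss, a fall with the mitochondrial mRNAs and not a gain. Reads that match both places and were counted at neither would not show in this test, and the counting options are not given. Doxycycline, which inhibits translation in mitochondria, cannot be told apart from the knockout, because 0 control libraries had doxycycline.

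Interferon-stimulated genes were higher as a list against control at the preset correlation, and missed the threshold with an estimated correlation (camera adjusted p = 0.561 at day 3 and 0.683 at day 5). Leaving out each library in turn does not decide whether 1 library of a day was the source. The list then passed at the preset correlation, which lies far below the estimated correlations of its members. The medians over the control mean were 0.002 and -0.002 in the controls themselves. They were 0.84 and 2.61 at day 3 and 0.439 and 1.98 at day 5, so all 4 KO-labelled libraries lay above both controls. The higher library of each day was replicate 2. KO day 5 replicate 1, at 0.439, was under the bound of 0.5 set for the test, which therefore stayed undecided. With members correlated at 0.917 and 0.911, how much of the rise the lower libraries hold is uncertain. GC content or length bias is argued against, since 94.1% or more of the median stayed once these trends were removed. Knockout, doxycycline and vector cannot be told apart, with 0 controls that had doxycycline.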

How the results depend on the processing

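Of all alternatives, removing GC and length trends was chosen after seeing the data; where a count moved with a setting the cause was not tested, except that leaving out libraries leaves fewer samples. Genes changed at day 3, day 5 and between the days numbered 2925, 3234 and 599 without a filter, and 254, 605 and 0 with limma on log2(FPKM + 1) without a filter, where 88 values of named genes and lists missed the threshold that they had passed. With only the compared groups fitted, 1315 changed at day 5. Higher and lower genes at day 5 numbered 864 and 1161 with GC and length trends removed, 1022 and 1105 with relative log expression factors, 1450 and 1784 without a filter, 1306 and 1456 with DESeq2 and 1016 and 726 with log2(FPKM + 0.1). Between the days DESeq2 gave 306, and limma on filtered FPKM 1 (pseudocount 1) and 0 (pseudocount 0.1). Leaving out each library gave 282 to 1906, 723 to 1874 and 1 to 15 genes, and CAMK2D values of -0.59 to 0.068 at day 3 and 0.28 to 0.97 at day 5.

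With the replicate number as a block the counts were 4064, 4418 and 1117 and CAMK2D at day 5 was 0.63 (edgeR adjusted p = 0.0198); the labels do not say what the number marks. Deviations of replicate 1 correlated at 0.468, 0.399 and 0.544 between the groups over 9127 genes. Of the genes called without the block, 1710 of 1710 at day 3 and 2117 of 2117 at day 5 were also called with it. Of the values for other named genes, 25 passed the threshold only with it, among them CAMKK2 at day 5 (-0.34, edgeR adjusted p = 0.0427). By camera the list of epithelial, stromal and HEK293-type markers at day 5 missed it (adjusted p = 0.0776). The lists that passed only with the block were p53 targets at day 3 (camera adjusted p = 0.0086), G2/M and immediate early genes at day 5 (0.0359 for both) and granule genes between the days (0.0128). The interferon list between the days had camera adjusted p = 8.3e-05 with it, and its median over the control mean was lower at day 5 under both numbers (0.835 to 0.439 and 2.61 to 1.977).

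Lists past the threshold numbered 1, 0 and 0 with estimated correlations, 7 at day 5 and 0 between the days with fry, and 11 between the days with unfiltered FPKM. At day 3 the apoptosis regulators passed with fry (adjusted p = 0.0216) but not with camera. Interferon-stimulated genes, JAK-STAT targets and G2/M genes passed with camera and missed the threshold with fry (adjusted p = 0.237, 0.115 and 0.355). Leaving out each library gave 10 to 15, 11 to 13 and 5 to 7 lists.

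Among the named genes and lists, the directions that turned were of genes that missed the threshold at that day, and of the interferon list between the days. Of all 2117 genes called at day 5, 2 turned with GC and length trends removed. The interferon list's adjusted p was 0.198 and 0.535 with the other sign without KO day 3 replicate 2 and KO day 5 replicate 1, and 4.09e-11 without KO day 5 replicate 2. At day 3 the turned log2 values without control replicate 1 were CAMK2D 0.068, CAMKK2 -0.02, JUN 0.035, CIITA -0.074 and CCNE1 0.021. Without control replicate 2 they were CAMK2B 0.43, HLA-DQB1 4.09 and HMMR -0.041. Without KO day 3 replicate 1 they were HLA-DQB1 0.658, CCNE1 0.051, HMMR -0.22 and HIST1H1B -2.30, and without KO day 3 replicate 2 CXCL2 -0.009 and MCM7 0.01. With the replicate block HLA-DQB1 was 0.195. The other ends of these ranges were CAMK2B -5.38, CAMKK2 0.182, JUN -0.203, CIITA 0.86, CXCL2 1.19, HLA-DQB1 -2.05, CCNE1 -0.124, MCM7 -0.195 and HIST1H1B 3.64. At day 5 HLA-DQB1 ranged from -0.967 without KO day 5 replicate 2 to 4.85 and was -0.292 without control replicate 1. ITGA2B ranged from -1.18 to 0.899 without control replicate 2, and was 0.535 without KO day 5 replicate 1, 0 with unfiltered FPKM and 0.01 with GC and length trends removed. GP9 ranged from -1.18 to 0.065 without KO day 5 replicate 1. Depth limits ITGA2B, which had 0 to 16 counts per library. HLA-DQB1 had 1, 6 and 12 counts under replicate number 1 and 53, 38 and 64 under number 2, and the cause was not tested.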

Other observations

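The lists and predictions of this part were written after the first results were seen; both tests named as hypotheses were set down before their own results. Genes for protein synthesis were higher at day 3. Of 83 cytosolic ribosomal proteins 12 rose and 0 fell (median log2 fold change 0.42, camera p = 4.87e-12, and p = 0.204 with an estimated correlation), and of 77 mitochondrial ribosomal proteins 12 rose and 1 fell (0.36, camera p = 1.57e-07, and p = 0.233 with an estimated correlation). At day 5 the medians were 0.17 (camera p = 0.00521, and p = 0.559 with an estimated correlation) and 0.21 (camera p = 0.00933, and p = 0.514 with an estimated correlation). Ribosomal proteins held 13.4% ± 1.88 of counts in the controls, 17.3% ± 0.051 at day 3 and 15.4% ± 0.0416 at day 5 (SD, n = 2). Of 20 cytosolic tRNA synthetases 3 rose and 1 fell at day 3 (camera p = 0.00906, and p = 0.278 with an estimated correlation), and 3 rose and 1 fell at day 5 (camera p = 0.251).

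A hypothesis drawn from HMOX1, FTH1 and GCLM was that targets of NRF2, the transcription factor of the oxidative stress response, rise as a set from day 3 to day 5. In 24 targets not looked at before, the median log2 fold change between the days was 0.35 (camera p = 8.99e-06, and p = 0.0291 with an estimated correlation), with 18 positive and 0 past the edgeR threshold alone. This is consistent with the hypothesis, found and tested on the same libraries. Against control 7 of them rose and 1 fell at day 3, and 11 rose and 1 fell at day 5, among them OSGIN1 (2.85, SE 0.36), FTL (1.2009, SE 0.16) and GCLC (1.03, SE 0.17).

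A second hypothesis, that nuclear genes for subunits of oxidative phosphorylation fall with the mitochondrially encoded mRNAs, was not borne out. A subunit that the first form of the list missed, COX4I1, was added after its result had been seen. The 74 subunits were higher as a list at day 3, with 7 up and 0 down (median 0.26, camera p = 2.83e-05, and p = 0.348 with an estimated correlation), and at day 5 the median was 0.07 (camera p = 0.151).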
